A study of Mus musculus with 2 samples.

How the data were processed

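Total RNA from the pancreas of male C57BL/6 mice aged 5 weeks was labelled with Cy3 and hybridised to Agilent 1-colour mouse arrays, per the labels. The WT group had 1 array and the Nrdc-cKO group had 1 array, so a group's array stands for 1 sample. The groups were taken from the sample titles. Both arrays were on 1 slide and read in the same scan, per the file headers, so slide and scan did not differ between the groups.

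The deposited scanner files gave, per spot, a processed intensity on a linear scale that Agilent Feature Extraction had corrected for background and spatial trend, per the file headers. These intensities were not normalized between arrays. The median pixel intensity and its local background, and the flags for saturation, outliers and signal well above background, came from the same deposited files. The software version was 12.0.3.1 per the file headers and 11.5.1.1 per the submitters' processing notes. The authors' deposited value table held the processed intensity of each non-control spot multiplied by 1 constant per array, 4.37 for WT and 1.92 for Nrdc-cKO, on a linear scale and without centring. Its medians were 42.5 for WT and 66.0 for Nrdc-cKO, and how the constants were chosen is not given in the sources used here.

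Each array had 62976 spots, of which 59305 were not controls and stood for 56605 probes. A set of 300 probes had 10 repeat spots each. Spots flagged as outliers on either array (80 on WT and 74 on Nrdc-cKO) were left out, which left 56604 probes. No spot was saturated on either array. The processed signal was put on a log2 scale, repeat spots of a probe were averaged, and the 75th percentile over all non-control probes of the array was subtracted. A probe counted as detected when at least 0.5 of its spots were well above background. A gene's value was the mean of the log2 differences, Nrdc-cKO minus WT, over its probes detected on both arrays, and the threshold was a log2 difference of 1.0 either way, which is 2-fold.

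Genes were named by matching the RefSeq accession of a probe, without versions, to a RefSeq gene table of assembly GRCm38.p6, which was used for names and gene order only. The array design refers to another build, so no coordinates are given. Of 35885 probes with a RefSeq accession, 32993 (91.9%) matched, for 22911 genes. The other 23611 probes had no gene name here and entered no gene result. The table lists the targeted gene under its older symbol, and the symbol Nrdc was used throughout. Of the 3933 genes with over 1 measured probe, 872 had probes that differed in sign, but only 3 of the 788 such genes past 2-fold did. The median range between probes of a gene was 0.27 on the log2 scale. Probes for near-identical family members, such as the amylases, trypsins and Reg proteins, can take up each other's transcripts, so values of single members of these families are uncertain.

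A gene with detected probes on only 1 array was given a bound. The bright array's level was set against the higher of the lowest detected signal on the dim array and the probe's own signal there, and the ratio is written as at least N-fold. A further 13 genes were detected on both arrays through different probes only and were given no value.

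With 1 array per group there is no estimate of the spread between animals, no test and no p-value, and every difference describes these 2 arrays. The only error available was technical. The SD of the log2 difference between repeat spots of a probe had a median of 0.032 over 286 probes, with a 95th percentile of 0.072. It leaves out animal, dissection, RNA extraction and labelling.

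Before the data were examined, 34 gene lists with 735 genes were fixed, 12 of them as main lists and the rest as other cell types, RNA quality and stress. Of these genes, 10 were in over 1 list and 17 had no named probe. The median log2 difference of a list was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins, and a list is called apart from these when it lay under the 2.5 or over the 97.5 percentile. This describes a list on these arrays and is no test across animals. Random lists were drawn gene by gene, while genes of a cell type, family or pathway can vary together. A list can therefore stand apart more readily than its percentile says, and most lists here did stand apart. A listed gene was at first matched by its listed symbol and given aliases only. After the list medians had been seen, matching through unique synonyms was added, which brought in Spink1, listed under its older name Spink3, in 2 lists. It changed the call of 1 list, the stress and acute-phase proteins, and both values are given.

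The rule for named genes was fixed at the same time. It took Nrdc, the 12 highest and 12 lowest genes whose probes had the same sign and whose sign held under normexp with quantile scaling and in the value table, the 5 largest bounds each way, in both cases without symbols of clones, predicted genes or accessions (such as Gm or Rik names), and up to 4 members of each list with the largest difference past 2-fold, or 2 members where none passed. A few genes that the rule or a list count would name are not reported here. The normexp condition was applied on the median signal in place of the planned mean. Genes named outside the rule are said to be chosen after their values were seen.

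The alternatives were quantile scaling, the 75th percentile or the median over probes detected on both arrays, loess on mean level with a span of 0.3, scaling on the spike-in probes, the authors' value table, no filter on dim probes, only probes at least 4 times the lowest detected signal, the brightest probe per gene, saturated or outlier spots kept, thresholds of 1.5-fold and 4-fold, and the mean of a list in place of its median. Chosen after seeing the data were normexp with an offset of 50 on the median signal, followed by 75th percentile or quantile scaling, bounds entered into list medians, and Spink1 left out.

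The steps were tested on simulated data made from the levels of the WT array, with 200 of 12007 genes changed by 2.0 on the log2 scale. All 100 higher and all 100 lower simulated genes were recovered past 2-fold, and 7 of 11787 unchanged genes passed. The simulation used a constant offset and normal noise of a chosen SD, with the same probes detected on both arrays. These counts follow from that SD, so they check the steps and give no error rate for the real arrays. A shifted list of 20 genes was placed at the 100th percentile, and 5 of 200 unchanged lists were called apart. The unchanged lists were random genes with independent noise, so this count follows from the percentile limits and gives no error rate for the real lists. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.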

Results

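The series profiled gene expression in whole pancreas of mice that lacked nardilysin, a metalloendopeptidase encoded by Nrdc, in cells with a history of Ptf1a expression, to ask what nardilysin does in the exocrine gland. In these mice Cre recombinase under Ptf1a, a transcription factor of pancreatic progenitors and acinar cells, removes the loxP-flanked Nrdc alleles. The pancreas of 1 WT male and 1 Nrdc-cKO male, both aged 5 weeks, was measured on 1 array each. Of the non-control spots, 46.3% were well above background on the WT array and 60.3% on the Nrdc-cKO array. There were no replicates, so the differences below have a size but no error across animals, and the number of arrays limits their precision.

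Nrdc itself was lower on the Nrdc-cKO array, with a log2 difference of -3.21 (9.25-fold lower), measured by 1 probe. Its level was 1.93 on the WT array and -1.28 on the Nrdc-cKO array, on the log2 scale relative to each array's 75th percentile. The alternatives kept this direction, with -1.32 under spike-in scaling as the smallest difference. The labels do not give the deleted part of the gene, and a probe outside it would not check the genotype.

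Of 13001 genes measured on both arrays, 1666 (12.8%) were at least 2-fold higher on the Nrdc-cKO array and 2252 (17.3%) at least 2-fold lower. At 4-fold the counts were 485 and 390. A further 2834 genes were detected on the Nrdc-cKO array only, 630 of them with a bound of at least 2-fold, and 200 were detected on the WT array only, all 200 past that bound. After scaling, the lowest detected level was lower on the Nrdc-cKO array, which makes this bound easier to reach for genes on the WT array only. The log2 levels of the arrays had a Pearson r of 0.882 across genes, which are not independent replicates. The balance of higher and lower genes depended on the scaling. The higher genes were 42.5% of those past 2-fold in the main scaling, 53% with the 75th percentile over detected probes, 53.8% with loess, 58.0% with normexp and quantile scaling, 72.9% in the authors' value table and 98.9% with spike-in scaling, which gave 10332 higher and 118 lower genes. Relative to the main scaling, in which the median gene stood at -0.18, the median of all genes moved by 0.50 in the value table and by 1.88 with spike-in scaling, and by 0.06 to 0.21 with the other scalings on the log2 scale. With spike-in scaling each gene stands 1.88 higher, so a gene given below as lower by less than this is higher there. Directions below are therefore relative to the bulk of genes on each array.

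**Figure D1:**
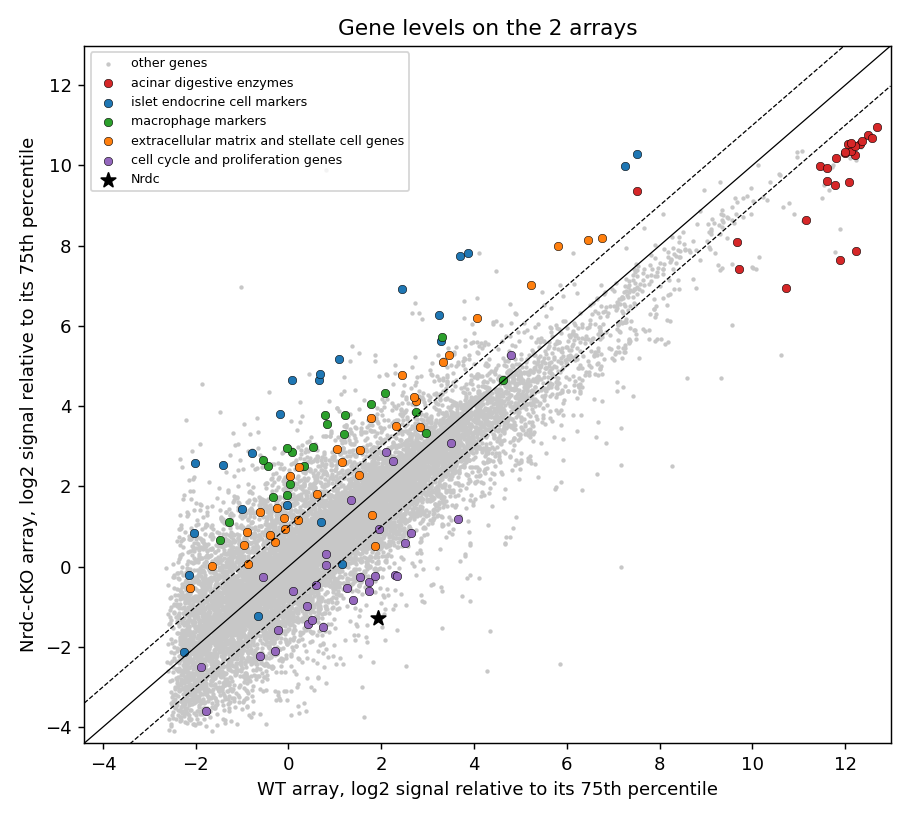
Level of each gene on the WT array (x axis) and the Nrdc-cKO array (y axis), as log2 signal relative to the array's 75th percentile, with 1 point per gene measured on both arrays. The solid line marks equal levels and the dashed lines 2-fold. Islet, macrophage and matrix genes lie mostly above the diagonal and cell cycle genes and 24 of 25 digestive enzymes below it, a position the enzymes lose with quantile scaling (median 0.00) and, like the cell cycle genes (0.087), with spike-in scaling (0.14).

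The acinar digestive enzymes, the main product of the exocrine gland, were lower on the Nrdc-cKO array relative to other genes. Of 25 measured, 24 were at least 2-fold lower, and the list median of -1.74 was below all 10000 random lists matched in bins of level. The largest differences were in the chymotrypsin-like protease Ctrl (-4.36), the pancreatic lipase Pnlip (-4.25), the ribonuclease Rnase1 (-3.79) and the kallikrein Klk1 (-2.53). The exception, chosen after its value was seen, was Prss1, a trypsinogen, at 1.85, and members of this family can take up each other's transcripts. Before scaling, the list median was -0.06, against 1.42 for all probes detected on both arrays and 0.64 for those with a mean log2 signal of 16 to 20, near the level of most of these enzymes. Only 131 probes had such a level and each bin held more genes than that. The match was therefore coarse here, and the distance from random lists may be overstated. The list median was 0.00 with quantile scaling, no longer apart from random lists (46.7 percentile, and 45.9 with normexp and quantile scaling), -0.61 with loess and 0.14 with spike-in scaling.

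Genes of the zymogen granule, secretagogue response and acinar transcription were lower as well. Of 25 measured, 15 were at least 2-fold lower and 1 higher, with a median of -1.30, below all 10000 random lists, although the median was 0.59 with spike-in scaling and between -0.63 and -0.80 with quantile scaling, loess, normexp or the value table. The water channel Aqp12 stood at -4.34, the granule membrane protein Gp2 at -3.93, and the acinar transcription factors Ptf1a and Bhlha15 (Mist1) at -2.72 each. Ptf1a is also the gene under which Cre is expressed in the Nrdc-cKO mice, and whether this affects its value was not tested. The gene past 2-fold in the other direction, chosen after its value was seen, was the secretin receptor Sctr at 1.01.

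Genes of the unfolded protein response, which supports the heavy secretory load of acinar cells, had a median of -1.01, above 1 of the 10000 random lists. The median was 0.88 with spike-in scaling, -0.51 in the value table and -0.54 with normexp and the 75th percentile. Of 30 measured, 15 were at least 2-fold lower and 2 higher. Derl3, a component of endoplasmic reticulum degradation, stood at -4.63, Fkbp11 at -3.55 and asparagine synthetase, Asns, at -2.42. The stress-induced factor Atf3 went the other way at 2.35, as did Ddit3, chosen after its value was seen, at 1.42.

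Cell cycle genes were lower too. Of 31 measured, 21 were at least 2-fold lower and 0 higher, with a median of -1.80, below all 10000 random lists, although the median was 0.087 with spike-in scaling, and -1.11 and -0.85 with normexp and 75th percentile or quantile scaling. The mitotic genes Birc5 (-2.57), Cdc20 (-2.50), Mki67 (-2.47) and Aurka (-2.33) had the largest differences.

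Markers of islet endocrine cells were higher on the Nrdc-cKO array. Of 23 measured, 19 were at least 2-fold higher and 1 lower, and the median of 3.04 (8.23-fold) was above all 10000 random lists. Pancreatic polypeptide (Ppy, 4.59), the granins Chgb (4.58) and Chga (4.47) and secretogranin Scg2 (4.13) had the largest differences. Insulin (Ins1, 2.72, and Ins2, 2.77) and glucagon (Gcg, 4.04), chosen after their values were seen, were in the same direction.

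Ductal markers had a median of 0.62 (1.11 in the value table), above all 10000 random lists, with 7 of 20 at least 2-fold higher and 3 lower. Ambp (3.71), osteopontin (Spp1, 2.88) and the bicarbonate transporter Slc4a4 (2.04) were higher, and the mucin Muc1 (-2.25) was lower. The keratin Krt19 and the transcription factor Sox9, chosen after their values were seen, stood at 0.25 and 0.36. Genes linked to acinar-to-ductal metaplasia and injury had a median of 1.14, above all 10000 random lists, but went both ways, with 9 of 17 at least 2-fold higher and 4 lower. Cd44, a cell surface receptor for hyaluronan, was higher at 2.17, with its 2 probes at 1.11 and 3.24, and the secreted trefoil factor Tff2 (-5.34), Agr2 (-3.72) and the mucin Muc5ac (-2.12) were lower. The list median was 0.46 with no filter on dim probes, and its mean, 0.23, was not apart from random lists, at the 94.4 percentile.

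Matrix and stellate cell genes were higher, with 27 of 34 measured at least 2-fold higher and 1 lower, and a median of 1.53 (2.88-fold), above all 10000 random lists. Lumican (Lum, 2.33), the matrix metalloproteinase Mmp2 (2.25), the growth factor receptor Pdgfra (2.21) and collagen Col1a2 (2.18) had the largest differences. Col14a1, chosen after its value was seen, was the lower member at -1.34.

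Macrophage markers were higher in 19 of 21 measured genes and lower in 0, with a median of 2.28 (4.85-fold), above all 10000 random lists. Ms4a7 (3.21), Marco (2.98), Aif1 (2.98) and Mpeg1 (2.94) led the list. Cytokines and chemokines had a median of 2.5, above all 10000 random lists, with 14 of 15 measured genes at least 2-fold higher. The chemokines Ccl5 (5.01), Ccl12 (4.02), Ccl7 (3.96) and Cxcl10 (3.71) had the largest differences among those measured on both arrays. A further 10 list members were detected on the Nrdc-cKO array only, 8 with a bound of at least 2-fold. Among these was Ccl8, chosen after its value was seen, at least 62.5-fold higher. Antigen presentation genes had a median of 2.58, with 13 of 15 higher, led by the MHC class II genes H2-Ab1 (4.13) and H2-Aa (4.03), their transactivator Ciita (4.05) and the invariant chain Cd74 (3.81). Interferon response genes had a median of 1.79 (1.19 with normexp and quantile scaling), with 17 of 21 higher, among them Ifi27l2a (2.85), Oas1a (2.70), Irf7 (2.52) and Oasl1 (2.38). Both lists were above all 10000 random lists. Of 20 T cell markers, 6 were measured on both arrays, with a median of -1.0 at the 1.71 percentile, or 0.88 with spike-in scaling, and 12 were detected on the Nrdc-cKO array only, 11 of them with a bound above 0. The T cell median was 0.67 with these at their bound. With no filter on dim probes it was 0.83, higher and apart at the 99.3 percentile.

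Stress and acute-phase proteins were split. Of 16 measured, 7 were at least 2-fold higher and 5 lower, with a median of -0.06 at the 97.4 percentile, just short of the upper limit. Haptoglobin (Hp, 7.99) and lipocalin-2 (Lcn2, 4.38) were higher, and the Reg family members Reg3a (-3.91) and Reg3d (-3.54) were lower. Which cells gave these signals, fat cells included, was not tested. Without Spink1, which was matched only after the list medians had been seen, the median was 0.48 at the 99.9 percentile. With Spink1 kept, the list was higher and apart with quantile scaling (0.82), loess (0.52), no filter on dim probes (0.85), normexp and quantile scaling (0.82) or the mean (0.25), and not apart with bright probes only (-0.62, at the 45.4 percentile), so its call depends on the setting.

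EGF receptor ligands and genes of ectodomain shedding, a process that nardilysin is known to enhance, had a median of 0.48, above 9799 of 10000 random lists. Of 13 measured, 4 were at least 2-fold higher and 1 lower. The ligand Egf was at -2.87, and the protease Bace2 (2.55), the metalloproteinase Adam8 (2.04) and the receptor Egfr (1.35, with 3 probes from 0.50 to 2.02) were higher. The median was 0.97 in the value table and 0.28 with no filter, and the mean, 0.46, was not apart from random lists, at the 95th percentile.

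**Figure D2:**
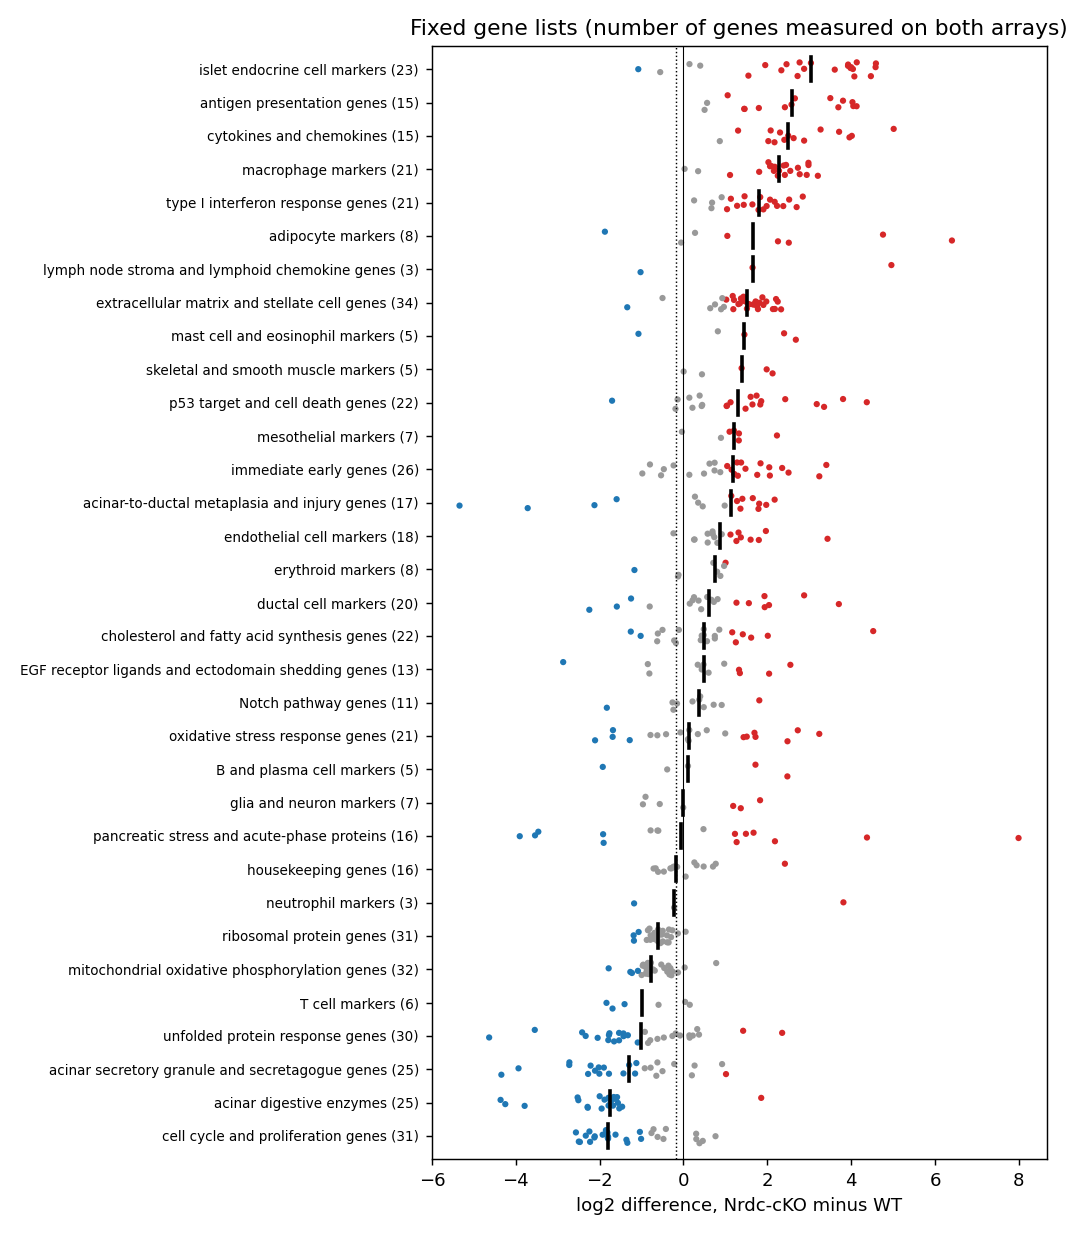
Log2 difference, Nrdc-cKO minus WT (x axis), of each gene measured on both arrays, by fixed list (y axis, number of genes in parentheses). Red and blue points are at least 2-fold higher and lower, black bars are list medians, and the dotted line is the median of all genes, -0.18. Islet markers have the highest median, 3.04, and cell cycle genes the lowest, -1.80, which turns to 0.087 with spike-in scaling.

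Adipocyte markers were higher on the Nrdc-cKO array, beside the groups above. Of 8 measured genes, 5 were at least 2-fold higher and 1 lower, with a median of 1.65, above all 10000 random lists, and 11 more were detected on the Nrdc-cKO array only. The median was 3.88 with these at their bound, 4.19 with no filter on dim probes and 1.05 with bright probes only. Plin4, a lipid droplet protein, stood at 6.40 and Dgat2, an enzyme of triglyceride synthesis, at 4.76. Adipsin (Cfd) was at least 1360-fold higher, Car3 at least 518-fold, Cidec at least 278-fold and adiponectin (Adipoq) at least 167-fold. Immediate early and heat shock genes, which can respond to tissue handling, also differed, with a median of 1.18, 15 of 26 at least 2-fold higher and 0 lower, led by Hspa1a (3.41), Hspa1b (3.24) and Egr2 (2.51).

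**Figure D3:**
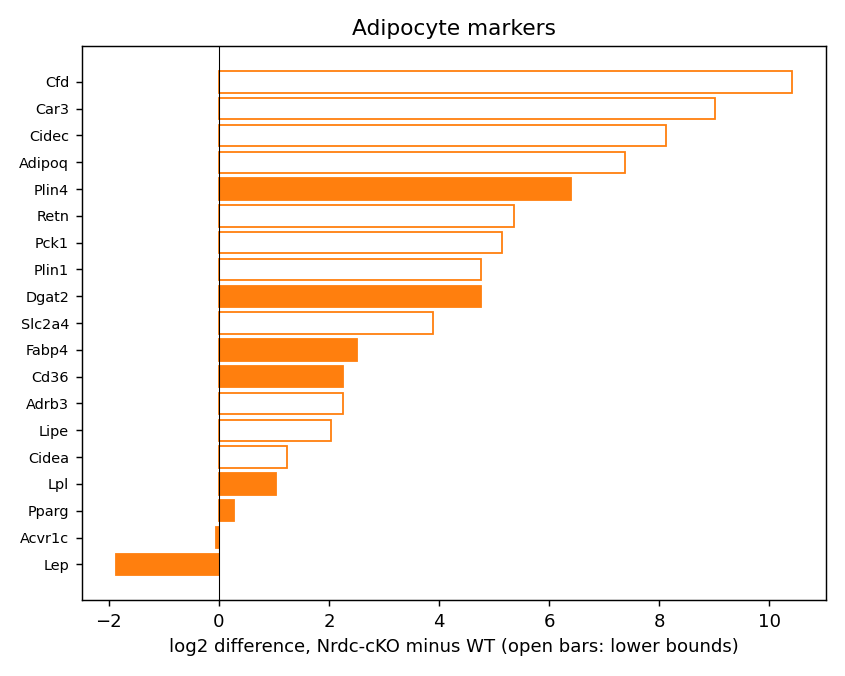
Log2 difference, Nrdc-cKO minus WT (x axis), of the adipocyte markers (y axis). Filled bars are genes measured on both arrays and open bars are lower bounds for the 11 genes detected on the Nrdc-cKO array only, with Cfd at a bound of at least 1360-fold.

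Among single genes measured on both arrays, Hp had the highest difference of those the rule could name, at 7.99, followed by Plin4 (6.40), the cytochrome Cyp2e1 (5.88), complement factor I (Cfi, 5.32), Ccl5 (5.01), the receptor Gpr182 (4.96), the lymphotoxin Ltb (4.96), the non-coding RNA Pvt1 (4.79), Dgat2 (4.76), Ppy (4.59), Chgb (4.58) and the desaturase Scd1 (4.53). The lowest were Hamp2, a hepcidin family gene, at -8.26, the neuropeptide galanin (Gal, -7.18), Lce1c (-6.89), the ATP-gated channel P2rx3 (-5.96), the amino acid transporter Slc38a5 (-5.77), Tff2 (-5.34), Gphb5 (-5.02), Sdk2 (-4.85), Padi2 (-4.78), the small nucleolar RNA Snord17 (-4.64), Derl3 (-4.63) and nonagouti (a, -4.58). Each of these rested on 1 probe. Ahsg was at least 361-fold higher and detected on the Nrdc-cKO array only. On the WT array only, Tmed11 was at least 111-fold, Bglap 26.5-fold, Chrdl2 25.9-fold, Tnfsf18 25.8-fold and Serpinb9e 25-fold brighter.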

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

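Both results here come from probes outside the gene comparison and were looked at only after the data had been seen. They are given as values, and no explanation was tested for either.

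The arrays carry 96 control probes for external ERCC transcripts, and the labels name no such addition. Over these probes the median signal was 2.82 on the WT array and 3.17 on the Nrdc-cKO array, and 44 had no spot well above background on either array. The probe ERCC-00079_170 had a mean signal of 588 on the WT array, with 28 of 28 spots well above background, and of 5.76 on the Nrdc-cKO array, with 2 of 28.

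Of 23611 probes without a gene name here, 3840 were detected on the Nrdc-cKO array only and 248 on the WT array only. Over all 56604 probes, named or not, these counts were 8737 and 507, so the imbalance in detection was not particular to the unnamed probes. Of the 6579 detected on both arrays, 356 were at least 2-fold higher and 1755 at least 2-fold lower on the Nrdc-cKO array.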

How the results depend on the processing

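No paired analysis was possible because each group had 1 array. Leaving out a replicate and other splits of the samples were not possible either. Normexp on the mean signal was planned and not run, since the scanner files used here hold the median signal, and normexp on that was added after the data had been seen, as were bounds in list medians and leaving out Spink1. Keeping saturated spots changed nothing, because none was saturated. The islet, macrophage, matrix, ductal and cytokine lists kept their direction in every alternative run and their place outside the random lists in every alternative for which it was computed, which leaves out the medians with bounds, with islet medians from 2.82 to 4.93 (mean 2.78) and macrophage medians from 2.10 to 4.16. Signal over background limits the lists with many genes detected on the Nrdc-cKO array only, 9 of 13 for neutrophils, 12 of 18 for B cells, 12 of 20 for T cells and 11 of 20 for adipocytes. Where no cause is named, the cause was not tested.

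Nrdc stayed lower, at -3.17 with quantile scaling, -3.05 with the 75th percentile over detected probes, -3.15 with their median, -3.08 with loess, -1.32 with spike-in scaling, -2.71 in the value table, and -2.23 and -2.20 with normexp followed by 75th percentile and quantile scaling. Genes at least 2-fold higher, 1666 in the main setting, numbered 10332 with spike-in scaling, 2888 in the value table, 3108 with no filter and 949 with bright probes only. Genes at least 2-fold lower, 2252 in the main setting, numbered 118 with spike-in scaling, 1074 in the value table, 8013 with no filter, and 1146 and 847 with normexp and 75th percentile or quantile scaling. Higher and lower genes numbered 2617 and 4065 at 1.5-fold, and 485 and 390 at 4-fold, by construction of the threshold.

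With spike-in scaling, which adds about 1.88 to every gene, medians turned to 0.14 for digestive enzymes, 0.59 for granule genes, 0.88 for the unfolded protein response, 0.087 for the cell cycle and 0.88 for T cell markers. The first 4 of these lists stayed below nearly all random lists there, and T cell markers stayed at the 1.71 percentile. The comparison with random lists is unaffected by a constant. With quantile scaling the digestive enzymes stood at 0.00, with and without normexp, since the brightest ranks of both arrays are given equal values, and were no longer apart (46.7 and 45.9 percentile). The T cell median was also above 0 with no filter, at 0.83 (99.3 percentile, so apart in the other direction), and with bounds, at 0.67. Granule genes stood at -0.65 with quantile scaling, -0.73 with loess, -0.80 in the value table and -0.80 and -0.63 with the normexp settings, cell cycle genes at -1.11 and -0.85 with the latter, the unfolded protein response at -0.51 in the value table, and digestive enzymes at -0.61 with loess. Lists that stayed apart but moved over 1.5 times included oxidative stress (0.69 with loess), erythroid (0.37 with the mean, 1.25 in the value table), endothelial (1.36 in the value table), cholesterol synthesis (0.98 in the value table), adipocyte (1.05 and 4.19), muscle (lowest 0.58) and mast cell (lowest 0.65) markers. Among the other lists, 4 gained and 2 lost their place apart under an alternative, and T cell markers lost theirs with the mean (-0.89). With the mean in place of the median, the metaplasia list (0.23) and the EGF receptor list (0.46) were no longer apart. The stress and acute-phase list, not apart in the main setting, was higher with quantile scaling (0.82), loess (0.52), no filter (0.85), normexp with quantile scaling (0.82), the mean (0.25) and without Spink1 (0.48), and stood at -0.62 with bright probes only.

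Of the named genes, 16 lower ones turned higher with spike-in scaling, by that same constant: Elane 0.71, Cd6 0.048, Cd247 0.19, Cd3e 0.48, Glycam1 0.86, Kit 0.81, Ndufa1 0.10, Sdhb 0.62, Atp5o 0.66, Uqcrfs1 0.80, Klf1 0.72, Krt20 0.29, Rplp1 0.70, Rpl32 0.70, Rpl38 0.81 and Lfng 0.057.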

Other observations

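The tests with spike-in probes, of islet against endothelial markers, of adipocyte genes and of T cell genes below were chosen only after the result was seen. Several further lists stood apart in the main setting. Target genes of p53 and cell death genes had a median of 1.30, above all 10000 random lists, with 14 of 22 at least 2-fold higher and 1 lower. The cell cycle inhibitor Cdkn1a was at 4.37, Phlda3 at 3.81, and the inflammatory caspases Casp1 and Casp4 at 3.35 and 3.18. Endothelial markers had a median of 0.86, with 8 of 18 higher, led by Prox1 (3.44), a gene that islet and duct cells also express, and Vwf (1.97), Cldn5 (1.80) and Lyve1 (1.60). Cholesterol and fatty acid synthesis genes had a median of 0.48, with 6 of 22 higher and 2 lower. The fatty acid enzymes Scd1 (4.53), Acaca (2.01) and Fasn (1.61) were higher. Adipocyte markers were higher too (median 1.65), and whether fat in the sample gave part of this was not tested. Oxidative stress genes went both ways around a median of 0.14, at the 97.8 percentile, with Me1 (3.24), Gpx2 (2.73) and Gpx3 (2.48) higher and the metallothionein Mt2 (-2.11) lower. Mesothelial markers had a median of 1.20 over 7 genes, with Igfbp5 (2.23), Rspo1 (1.32), Wt1 (1.32) and Lrrn4 (1.20), muscle markers 1.39 over 5 genes (0.61 with no filter, and 0.68 and 0.58 with the normexp settings), with Myh11 (2.13), Myl9 (1.98) and Synpo2 (1.39), mast cell markers 1.45 over 5 genes (0.82 with bounds, 0.80 with no filter, and 0.65 and 0.77 with the normexp settings), with Cma1 (2.68), Mcpt4 (2.40), Cpa3 (1.45) and Kit (-1.07), and lymphoid chemokine genes 1.65 over 3 genes (1.18 with bounds), with Ltb (4.96), Ccl21a (1.65) and Glycam1 (-1.02). Erythroid markers had a median of 0.76, with Hbb-b1 at 1.0 and Klf1 at -1.17. Kit, Glycam1 and Klf1 turned higher with spike-in scaling. The mesothelial list was no longer apart with normexp and the 75th percentile (0.73), nor the lymphoid chemokine list with no filter on dim probes (0.63).

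Other lists, except T cell markers (-1.0, at the 1.71 percentile), were not apart in the main setting. Housekeeping genes had a median of -0.19, with B2m at 2.42, ribosomal protein genes -0.61, with Rplp1 (-1.19), Rpl32 (-1.18) and Rpl38 (-1.07), and oxidative phosphorylation genes -0.79, with Ndufa1 (-1.78), Sdhb (-1.27), Atp5o (-1.23) and Uqcrfs1 (-1.09). All of these genes but B2m turned higher with spike-in scaling. Notch pathway genes had a median of 0.38, with Notch2 at 1.81 and Lfng at -1.83, glia and neuron markers -0.01, with Uchl1 (1.83) and Tubb3 (1.19), and neutrophil markers -0.22 over 3 genes, with S100a9 (3.82) and Elane (-1.18). A further 9 of 13 neutrophil genes were detected on the Nrdc-cKO array only, which gave a median of 0.32 with bounds. B cell markers had a median of 0.11 over 5 genes, with Blnk (2.48), Cd37 (1.72) and Pax5 (-1.92), and 1.95 with bounds. With no filter on dim probes the neutrophil (1.39), B cell (2.68) and glia and neuron (0.65) lists were higher and apart, as was the Notch list (0.43) with normexp and the 75th percentile. The T cell list also turned from lower and apart to higher and apart with no filter (0.83, at the 99.3 percentile). Among the 6 T cell markers measured on both arrays, Cd6 (-1.84), Cd247 (-1.69) and Cd3e (-1.41) were lower. Spike-in scaling turned these genes higher, as well as Elane and Lfng. Another 12 of 20 T cell markers were detected on the Nrdc-cKO array only, 11 with a bound above 0 and 5 with a bound of at least 2-fold. Intestinal markers had 2 measured genes, with Krt20 at -1.59, and were given no percentile. Outside the naming rule, and chosen after its value was seen, 1810009J06Rik had a log2 difference of 9.10. Xist was detected on neither array, and the Y-linked genes Ddx3y, Eif2s3y and Kdm5d on both, which goes with the male sex in the labels.

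Before scaling, probes detected on both arrays were brighter on the Nrdc-cKO array by a median of 1.42 on the log2 scale (2.67-fold). The 8 spike-in probes detected on both arrays differed by -0.20 ± 0.04 (SD over probes). This argues against a difference in labelling, hybridisation or scanning that acts on all probes alike. Spike-in probes do not report the amount or integrity of the sample RNA, which were not tested and stay open. The 100 brightest probes held 42.6% of the summed signal on the WT array and 27.7% on the Nrdc-cKO array, a difference of 14.9 percentage points. A few abundant transcripts taking up more of the labelled RNA on the WT array may therefore account for part of the pattern. The summed signal itself was 4.26e+07 on the WT array and 7.21e+07 on the Nrdc-cKO array, which a shift in share alone would not give. The interquartile range of the difference at a mean log2 signal of 16 or more was 1.20 ± 0.097 (SD over probes drawn again) times that at 12 to 14, over the bound of 1 set beforehand, which argues against a plateau of the brightest probes, although by little more than 2 SD. At 14 to 16 the ratio, looked at afterwards, was 0.558. The median difference fell from 1.61 at a mean log2 signal of 6 to 8 to 0.64 at 16 to 20, also looked at afterwards, a fall in the direction that a plateau would give, so the weight against it is small. A change in the RNA content of the Nrdc-cKO tissue was not tested.

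Markers of many cell types other than acinar cells were higher on the Nrdc-cKO array. A lower acinar share would raise all of them alike if acinar cells lack these markers, which was not checked. The islet median exceeded the endothelial median by 2.18 on the log2 scale, and the interquartile ranges, 2.14 to 4.02 and 0.61 to 1.35, did not overlap. Macrophage markers (2.06 to 2.73) did not overlap the endothelial range either, but matrix genes (1.18 to 1.81) did. The islet list was already known to have the highest median, so this comparison cannot decide the question. The values show only that the rises were unequal on these arrays. Fat carried along at dissection cannot be told apart from fat cells within the gland, since the 11 adipocyte genes detected on the Nrdc-cKO array only are what both would give. Whether fat also gave part of the rise of genes outside the adipocyte list was not tested. Lymphoid tissue carried along cannot be told apart either. With bounds, the T cell (0.67) and B cell (1.95) medians were both higher, as such tissue would give. Without bounds they were -1.0 over 6 T cell genes and 0.11 over 5 B cell genes. The deletion of Nrdc, the factor the design names, stays among the open explanations, and with 1 array per group it cannot be separated from a difference between the animals. The WT title gives no Cre, so an effect of Cre under Ptf1a cannot be told apart from the deletion either, also with more animals.

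A further hypothesis was that genes over 16-fold apart might be variants carried along with the targeted alleles. Of 56 such genes, 0 were among the 200 measured genes nearest to Nrdc and Ptf1a, where 0.861 would be placed by chance, so variants near these loci are unlikely to account for them, and variants elsewhere in the genome were not tested.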
